A study of Dichomitus squalens with 6 samples.

How the data were processed

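Mycelium of the white-rot basidiomycete Dichomitus squalens, monokaryotic strain CBS 464.89, was grown for 5 days at 28 °C on agar plates (1.5%) of a low-nitrogen asparagine and succinate medium with 25 mM of cellobiose, L-rhamnose or xylose, per the labels' protocols. Total RNA from ground mycelium was made into Illumina libraries and sequenced. The labels give 2 replicates per sugar, 6 libraries in all. No library from plates without one of these sugars was analysed here. The labels do not say whether the replicates came from separate plates or cultures. The p-values of the edgeR, DESeq2 and limma tests thus measure only the spread between these samples, which may be technical. The permutation and Fisher's exact tests described below take genes as units, and their p-values do not measure that spread.

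The authors deposited one table per library with, for each gene, the coding length, an RSEM expected count and an FPKM value. An expected count is an estimated number of reads, which need not be whole because RSEM divides reads that match several genes among them. The deposited FPKM is the expected count scaled by the authors to gene length and library size. Bowtie2, HISAT and RSEM are named in the submitters' processing notes. Their versions, their settings, the genome build and whether counting used strand are not given in the sources used here. Genes without reads are left out of each table and were taken as 0. The deposited gene models are those of the JGI gene catalog of this strain, with 15295 models on 406 scaffolds. The lengths in the count tables equalled the summed coding parts of these models in 100% of entries, so the gene lengths behind FPKM, and by that the sequences counted, held coding sequence without UTRs, although 66.4% of models have an annotated UTR. Spans of adjacent models overlapped in 1784 cases, and spans of their coding parts in 25. Reads that lie wholly in UTRs would then not enter these values.

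The gene models carry positions and numeric identifiers, and the files do not pair these with product names. A RefSeq gene table of another strain of the species, LYAD-421 SS1, with 12497 genes, matched 0 of the identifiers and was not used. Before the data were examined, 33 gene lists built on product names had been fixed, with tests of each list and of product-name enrichment. With no product names, 0 of the lists could be formed and these tests were not run. The rule for named genes, also fixed before the data were examined, then allows at most 2 identifiers per direction and comparison. They are the genes with the greatest fitted log2 fold change among those past the threshold, with both libraries of one sugar above both of the other in CPM and a mean of at least 10 CPM on the higher sugar. Regions were described by position instead. Their rule was written after the absence of product names was seen. It takes, per comparison and direction, the 2 longest runs of at least 3 consecutive gene models that passed the threshold in the same direction with at least a 2-fold change, ties being settled by the median fold change.

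Expected counts were rounded to whole numbers. Totals per library ranged from 7306517 to 8126006. Of 14466 genes with a count in any library, 12667 passed edgeR's filterByExpr and were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit, glmQLFTest), with all 6 libraries in one fit and no covariate. The common biological coefficient of variation was 0.2183, with 3 residual degrees of freedom and 4.153 prior degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p, computed within a comparison, was under 0.05. Standard errors are the fitted log2 fold change divided by the square root of its F statistic. A gene was assigned to a sugar when both comparisons with that sugar passed in the same direction. Both comparisons use that sugar's libraries. The overlap expected of independent lists and the overlap in 20 simulated sets of unchanged groups were computed. With 2 libraries per sugar, each part of a split would hold 1 library, and no such split was made.

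Genes called next to each other were counted along the scaffolds and compared with 10000 permutations of the calls over the tested genes, one-sided, so that 0.0001 is the smallest p they can give. In the alternative fits and without single libraries 1000 permutations were used, with a smallest p of 0.001. Enrichment of called genes on each scaffold with at least 20 tested genes was tested with a one-sided Fisher's exact test, adjusted over scaffolds and directions within a comparison. That test takes genes as independent, whereas neighbouring genes were called together more often than permuted calls. The p-values of scaffolds may therefore be too small, and they are not separate from the results on neighbours. Genes with an expected count that was not whole (by more than 1e-06) in any library were taken as sharing reads with a similar gene. They made up 1062 of the tested genes (8.38%), and values of named genes among them are uncertain. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

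The test was checked on simulated counts drawn from the real means and library sizes of 12667 genes, with each gene's spread as estimated by edgeR. That spread was the same on all sugars. Real replicates differed unequally, with a chi-square per degree of freedom of 14.76 on L-rhamnose and 53.83 on xylose. The simulated shares of false calls therefore hold only for groups of equal spread. With 2500 genes changed in L-rhamnose against cellobiose, 55.8% of 2-fold and 95.1% of 4-fold changes were recovered, and 4.84% of the calls were false. For xylose against cellobiose, the same step gave 53.7%, 94.1% and 4.3%, and for L-rhamnose against xylose 55.8%, 94.4% and 4.33%. With only 200 genes changed, 4-fold changes were recovered in 88%, 85% and 83% of cases and 2-fold changes in 19%, 6% and 13%, and false calls made up 17.1%, 11.7% and 7.69%, in the same order of comparisons.

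The alternatives tried were DESeq2 size factors or library size alone in place of TMM, DESeq2 1.42.0 in place of edgeR, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in at least 2 libraries, no filter on low counts, at least 1 CPM in at least 4 libraries, a fit of only the 2 sugars compared, the replicate number as a block, a test against a minimum fold of 1.5, and each library left out in turn. For neighbouring genes, a wider neighbourhood, a gap of at least 1000 bases and the removal of genes that share reads were also tried.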

Results

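The transcriptome of Dichomitus squalens mycelium was compared between 3 carbon sources. Dichomitus squalens is a white-rot fungus that breaks down all major polymers of wood, and CBS 464.89 is a monokaryotic strain of it. Cellobiose is the glucose disaccharide released from cellulose, L-rhamnose is a deoxy sugar of pectin, and xylose is the backbone sugar of xylan. The series was set up to find candidate regulators of plant biomass breakdown from the response to simple carbon sources. With 2 libraries per sugar, the data allow 3 pairwise comparisons.

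Expected counts summed to 8004353 and 7898563 on cellobiose, 7306517 and 7736271 on L-rhamnose, and 8126006 and 7979043 on xylose. Each library listed between 13993 and 14115 genes with reads. The 10 most abundant genes of a library took 4.605% and 5.392% of the counts on cellobiose, 6.396% and 6.775% on L-rhamnose, and 4.237% and 3.998% on xylose. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 24.32 on cellobiose, 14.76 on L-rhamnose and 53.83 on xylose, so no 2 libraries held the same reads. This does not show whether they came from separate cultures. Across genes, which are not independent replicates, log2 CPM correlated between replicates with r = 0.981 on cellobiose, 0.9841 on L-rhamnose and 0.966 on xylose. Between sugars, r ranged from 0.8672 for an L-rhamnose and a xylose library to 0.951 for a cellobiose and a xylose library. A principal component holding 59.61% of the variance placed the L-rhamnose libraries at 63.663 and 59.91 and the xylose libraries at -59.218 and -31.485, with cellobiose between them at -7.089 and -25.781. The next component, with 23.3%, set the cellobiose libraries apart from the rest.

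**Figure D1:**
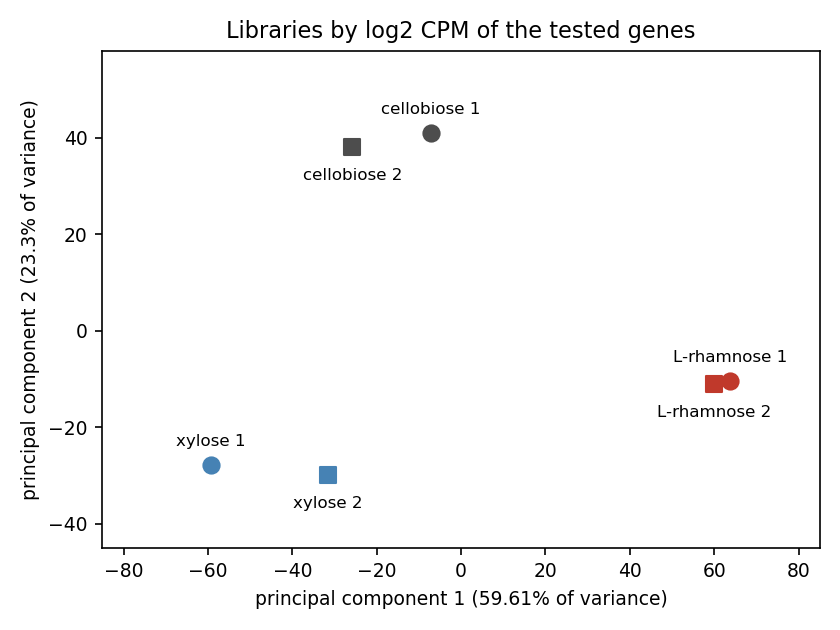
Scores of the 6 libraries on 2 principal components of log2 CPM over the tested genes, in arbitrary units, with colour for the sugar and marker shape for the replicate number. The L-rhamnose libraries lie at 63.663 and 59.91 on the horizontal axis, and the cellobiose libraries at 40.967 and 38.087 on the vertical axis.

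Growth on L-rhamnose and growth on cellobiose were compared to find genes that respond to the pectin sugar as against the cellulose sugar. Of 12667 tested genes, 2792 (22%) passed the threshold in edgeR's quasi-likelihood test, 1397 higher and 1395 lower on L-rhamnose. A change of at least 2-fold was found for 1072 of the higher and 834 of the lower genes. The gene model with the greatest rise was gene_8428, a model of 3 exons with a coding length of 309 bases at 277347 to 277982 on the minus strand of scaffold 26. It stood at 11949 ± 3271 FPKM (SD, n = 2) on L-rhamnose and 41.19 ± 7.135 on cellobiose, a log2 fold change of 8.16 ± 1.1 (SE, edgeR adjusted p = 0.00638). Next was gene_13361, a model of 21 exons with a coding length of 3021 bases at 86874 to 91338 on the plus strand of scaffold 80. It stood at 1306 ± 312.1 FPKM on L-rhamnose and 27.23 ± 13.64 on cellobiose (log2 fold change 5.56 ± 0.65, edgeR adjusted p = 0.00429, and 6.18 without cellobiose replicate 1). Both were also higher on L-rhamnose than on xylose, by 7.08 ± 1.05 and 4.45 ± 0.62 on the log2 scale (edgeR adjusted p = 0.0051 and 0.00423). Their xylose replicates differed widely, at 13.91 and 148.54 FPKM for gene_8428 and 27.36 and 80.95 for gene_13361. The size of these differences from xylose is therefore uncertain.

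Among the genes lower on L-rhamnose, the greatest fall was that of gene_13851, with 4 exons at 51777 to 53115 on scaffold 123. It stood at 1.155 ± 0.03536 FPKM (SD, n = 2) on L-rhamnose and 166.6 ± 49.41 on cellobiose, a log2 fold change of -7.23 ± 1.16 (edgeR adjusted p = 0.00938). Its counts were not whole in all 6 libraries, so it shares reads with a similar gene and its values are uncertain. Next was gene_16572, with 5 exons at 25118 to 26622 on scaffold 151, at 2.58 ± 1.697 FPKM on L-rhamnose and 223.3 ± 34.85 on cellobiose (log2 fold change -6.43 ± 0.48, edgeR adjusted p = 0.00135, and -7.38 without L-rhamnose replicate 2). On xylose this gene was at 2.265 ± 1.096 FPKM, and its log2 difference between L-rhamnose and xylose was 0.06 ± 0.53 (edgeR adjusted p = 0.936). Without 1 library, the call of gene_8428 was lost when cellobiose replicate 2 (edgeR adjusted p = 0.0633), L-rhamnose replicate 1 (0.0537) or L-rhamnose replicate 2 (0.0552) was left out. The call of gene_13851 was lost without the same libraries, at 0.0523, 0.0928 and 0.0872.

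Genes higher on L-rhamnose than on cellobiose lay side by side in 15 runs of at least 3 models with at least a 2-fold rise, against a mean of 5.38 and a highest of 16 runs among permuted calls, so part of the runs are expected by chance. Runs of lower genes numbered 13 (permuted mean 2.59, highest 11). Without cellobiose replicates 1 and 2, L-rhamnose replicates 1 and 2 and xylose replicates 1 and 2, in this order, the 15 runs became 5, 2, 0, 1, 26 and 25 and the 13 became 8, 0, 0, 0, 26 and 26. In a fit of only the 2 sugars they were 28 and 25, at a minimum fold of 1.5 they were 4 and 6, and DESeq2 gave 22 runs of lower genes. On scaffold 4, 6 consecutive models between 709635 and 725642 passed with at least a 2-fold rise, with a median log2 fold change of 1.55 and single values from 1.08 to 2.86. Their mean level was 229 and 204 FPKM in the L-rhamnose libraries and 52.9 and 37.3 in the cellobiose libraries, and 1 of the 6 shares reads with another gene. On scaffold 1, 5 consecutive models between 881493 and 894581 rose by a median of 2.35, from 13.6 and 9.85 FPKM on cellobiose to 68.9 and 56.7 on L-rhamnose. Runs of lower genes were found on scaffold 77, with 5 models between 44825 and 53043 (median log2 fold change -2.17), and on scaffold 123, with 4 models between 26700 and 39153 (median -3.78), 1 of which shares reads. The scaffold 123 models stood at 101 and 106 FPKM on cellobiose and 8.23 and 7.72 on L-rhamnose. When L-rhamnose replicate 1 or 2 was left out, most of the genes in each of these 4 regions no longer passed the threshold. The same held without cellobiose replicate 2, except on scaffold 123, and on scaffold 4 also without cellobiose replicate 1. In the fits without 1 library, the medians stayed between 1.34 and 1.84 on scaffold 4, between 2.11 and 2.52 on scaffold 1, between -2.51 and -1.99 on scaffold 77 and between -4.0 and -3.68 on scaffold 123.

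Of the called genes with a next model along the same scaffold, 16.3% of the higher and 16.4% of the lower ones were followed by a gene called in the same direction. Permuted calls gave means of 9.73% and 9.7% (permutation p = 0.0001 for both, the smallest that 10000 permutations can give). For neighbours at least 1000 bases apart the shares were 14.1% and 11.8%, against permuted means of 9.12% and 9.1% (permutation p = 0.0016 and 0.0466). With fewer genes called, both the shares and the permuted means fell. For higher genes they were 9.26% and 1.14% without cellobiose replicate 2, 2.73% and 0.791% without L-rhamnose replicate 1, and 5.56% and 1.02% without L-rhamnose replicate 2, still an excess (permutation p = 0.001, 0.042 and 0.001, from 1000 permutations, whose smallest p is 0.001). For lower genes they were 4.43% and 1.06% without cellobiose replicate 2 (permutation p = 0.002), and the share was 0.0% without either L-rhamnose library, where the permuted means were 0.307% and 0.317%. Scaffold 68 held 16 higher genes among 51 tested (31.4%, against 11% of all genes, Fisher's exact adjusted p = 0.0234) and scaffold 52 held 19 among 73 (26%, adjusted p = 0.0418). On scaffold 68 the share fell to 5.66%, 1.89%, 1.89% and 1.96% without cellobiose replicates 1 and 2 and L-rhamnose replicates 1 and 2 (adjusted p = 1.0 in each), where 542 of 13009, 163 of 13012, 111 of 12902 and 145 of 12961 tested genes were higher. The excess did not pass in a fit of only the 2 sugars (0.0644) or at a minimum fold of 1.5 (13.7%, adjusted p = 0.147) either. On scaffold 52 the share was 10.7% without cellobiose replicate 2 and 8.22% and 13.3% without L-rhamnose replicates 1 and 2, and it passed when any 1 library was left out (adjusted p from 3.23e-06 to 0.0121) but not with at least 1 CPM in 4 libraries (0.0785).

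The count of 2792 genes moved with single libraries. It was 1121 without cellobiose replicate 1, 322 without cellobiose replicate 2, 149 (111 higher and 38 lower) without L-rhamnose replicate 1 and 197 (145 and 52) without L-rhamnose replicate 2, in fits where the lone library is assumed to vary like the other groups. Without xylose replicates 1 and 2 it was 3791 and 3802. Higher genes made up 50.0% of the calls with all libraries, 74.5% and 73.6% without L-rhamnose replicates 1 and 2, and 44.9% (1435 higher and 1763 lower) with DESeq2.

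Xylose and cellobiose, the sugars of xylan and cellulose, gave the fewest changed genes with all libraries. The order turned without L-rhamnose replicate 1, with 186 genes against 149 for L-rhamnose minus cellobiose. In edgeR's test 533 genes (4.21%) passed, 210 higher and 323 lower on xylose, and 195 and 308 of them changed at least 2-fold. The genes with the greatest rise on xylose both lay on scaffold 99, within 21817 to 38344. The model gene_13409, with 10 exons at 21817 to 23314, stood at 2894 ± 351.5 FPKM (SD, n = 2) on xylose, 42.95 ± 0.8273 on cellobiose and 80.98 ± 15.38 on L-rhamnose, with a log2 fold change against cellobiose of 6.19 ± 0.26 (edgeR adjusted p = 0.000293). The model gene_13415, with 8 exons at 37192 to 38344, stood at 5086 ± 3079 FPKM on xylose and 105.6 ± 34.16 on cellobiose (log2 fold change 5.7 ± 0.59, edgeR adjusted p = 0.00492, and 4.91 without xylose replicate 2). Both had counts that were not whole in all 6 libraries, so they share reads with similar genes and their levels are uncertain.

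The greatest falls on xylose were larger. The 3-exon model gene_7552, at 269421 to 270086 on scaffold 21 with a coding length of 348 bases, went from 3412 ± 476.3 FPKM on cellobiose to 9.595 ± 1.195 on xylose (SD, n = 2), a log2 fold change of -8.35 ± 0.43 (edgeR adjusted p = 0.000601). The 4-exon model gene_9373, at 145828 to 146945 on scaffold 64 with a coding length of 345 bases, went from 2518 ± 783.2 to 13.78 ± 4.822 FPKM (log2 fold change -7.39 ± 0.42, edgeR adjusted p = 0.000845). On L-rhamnose these genes were at 1662 ± 717.8 and 328.9 ± 83.79 FPKM, lower than on cellobiose by edgeR (adjusted p = 0.0465 and 0.00372) and higher than on xylose (adjusted p = 0.000934 and 0.00137).

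Genes lower on xylose formed 3 runs of at least 3 models with at least a 2-fold fall (permuted mean 0.129, highest 3). They numbered 1 in a fit of only the 2 sugars, at a minimum fold of 1.5 and when any 1 cellobiose or L-rhamnose library was left out, 6 without xylose replicate 2 and 5 with DESeq2. In one of them, 3 consecutive models between 78628 and 83535 on scaffold 103 had a median log2 fold change of -3.23. Their mean level was 246 and 233 FPKM in the cellobiose libraries, 119 and 98.5 in the L-rhamnose libraries and 19.9 and 29.4 in the xylose libraries. A further 3 models between 18766 and 23387 on scaffold 76 had a median of -1.9. Most of these no longer passed in a fit of only the 2 sugars (median -1.92) or without any 1 cellobiose or L-rhamnose library (medians from -1.91 to -1.53). No run of at least 3 genes was found among the genes higher on xylose with edgeR, where DESeq2 gave 5 runs and the edgeR fits without xylose replicates 1 and 2 gave 1 and 6. Lower genes were followed by another lower gene in 9.69% of cases (permuted mean 2.23%, permutation p = 0.0001), and higher genes by another higher gene in 4.31% (permuted mean 1.47%, permutation p = 0.0036). For neighbours at least 1000 bases apart, the shares were 4.9% and 0.0% and the excess was no longer past the threshold (permutation p = 0.0621 and 1.0). The share of higher genes was 0.0% without cellobiose replicate 1, 7.35% without cellobiose replicate 2, 1.69% without L-rhamnose replicate 2 and 10.6% without xylose replicate 2, against permuted means of 0.191%, 0.384%, 0.414% and 3.81% (permutation p = 1.0, 0.001, 0.211 and 0.001, from 1000 permutations). It was 1.67% in the fit of only the 2 sugars (permuted mean 0.382%, permutation p = 0.202).

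Scaffolds 91, 176 and 76 held more genes lower on xylose than the 2.55% of all genes, with 15.2%, 25.0% and 16.2% of 46, 20 and 37 tested genes (Fisher's exact adjusted p = 0.0238, 0.0238 and 0.0332). Scaffold 91 no longer passed with DESeq2 (adjusted p = 0.148), library size only (0.0527), limma on log2(FPKM + 1) (0.0544) or without xylose replicate 2 (0.0834). Scaffolds 176 and 76 did not pass when any 1 library was left out, with adjusted p from 0.0615 to 1.0 and from 0.0648 to 0.392, nor in the fit of only the 2 sugars (1.0 and 0.0589), at a minimum fold of 1.5 (0.631 and 0.123) or with limma on log2(FPKM + 1) (0.0585 and 0.111). Scaffold 76 did not pass with DESeq2 (0.1) or limma on log2(FPKM + 0.1) (0.0881) either. The share on scaffold 176 was 0.0% in the fit of only the 2 sugars and without cellobiose replicate 1 or either L-rhamnose library, and 13% without cellobiose replicate 2. On scaffold 76 the share was below 16.2% as well without any 1 cellobiose or L-rhamnose library. Fewer of all genes were lower on xylose in these fits and in the fit of only the 2 sugars. Smaller shares alone therefore do not show a smaller excess on these scaffolds.

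The count of 533 genes rose to 1079 with DESeq2, of which 535 were higher and 544 lower, and fell to 191 in a fit of only the 2 sugars. It was 148 and 214 without cellobiose replicates 1 and 2, 186 and 182 without L-rhamnose replicates 1 and 2, and 791 and 1035 without xylose replicates 1 and 2. The split into higher and lower genes differed between settings. In edgeR, higher genes made up 39.4% of the calls with TMM factors, 40.4% with DESeq2 size factors and 28.9% (168 higher and 413 lower) with library size only, which moved the median log2 fold change of all genes from 0.006 to -0.117. They made up 28.0% with limma on log2(FPKM + 1) and 49.6% with DESeq2, where the test differs too.

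L-rhamnose and xylose, sugars of pectin and xylan, gave the most changed genes with all libraries in one fit. In fits of only the 2 sugars they gave 3348 genes, against 3705 for L-rhamnose minus cellobiose, and without xylose replicate 1 they gave 2806 against 3791. In edgeR's test 3988 genes (31.5%) passed, 2014 higher and 1974 lower on L-rhamnose, and 1595 and 1091 of them changed at least 2-fold. The greatest rise was that of gene_9595, a model of 11 exons with a coding length of 1113 bases at 176885 to 179203 on the minus strand of scaffold 52. It stood at 1121 ± 342.4 FPKM (SD, n = 2) on L-rhamnose, 27.74 ± 12.85 on cellobiose and 4.625 ± 2.171 on xylose, and its log2 fold change was 7.77 ± 0.55 between L-rhamnose and xylose (edgeR adjusted p = 0.00119) and 5.31 ± 0.48 between L-rhamnose and cellobiose (adjusted p = 0.00213). Next was gene_7552, described above as lowest on xylose, with 7.28 ± 0.41 (edgeR adjusted p = 0.000934).

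Of the genes lower on L-rhamnose, gene_12153, with 6 exons at 21030 to 21858 on scaffold 65, had 1 count in the L-rhamnose libraries together and 494 on xylose. The ratio was 461, with a 95% interval of 82.4 to 18261 that covers counting error only. On cellobiose gene_12153 stood at 1.72 ± 2.065 FPKM. It was not called between L-rhamnose and cellobiose (edgeR adjusted p = 0.308) but was higher on xylose than on cellobiose (adjusted p = 0.0353). Its xylose replicates differed widely, at 106.02 and 22.09 FPKM, and the call (edgeR adjusted p = 0.00699) was lost without L-rhamnose replicate 1 (0.0662) or 2 (0.0636). Its fitted log2 fold change was -8.68, and from -11.0 to -7.13 without 1 of the L-rhamnose or xylose libraries. The 3-exon model gene_14168, with a coding length of 234 bases at 35699 to 36058 on scaffold 96, stood at 560.9 ± 197.3 FPKM on xylose and 1.66 ± 2.348 on L-rhamnose (log2 fold change -8.51 ± 1.1, edgeR adjusted p = 0.00353). With 5 and 0 counts in the L-rhamnose libraries the size of this change is uncertain. The log2 fold change was -12.9 without L-rhamnose replicate 1 and -7.53 without replicate 2. On cellobiose gene_14168 stood at 16.28 ± 18.74 FPKM. It too was not called between L-rhamnose and cellobiose (edgeR adjusted p = 0.106) but was higher on xylose than on cellobiose (adjusted p = 0.0192).

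**Figure D2:**
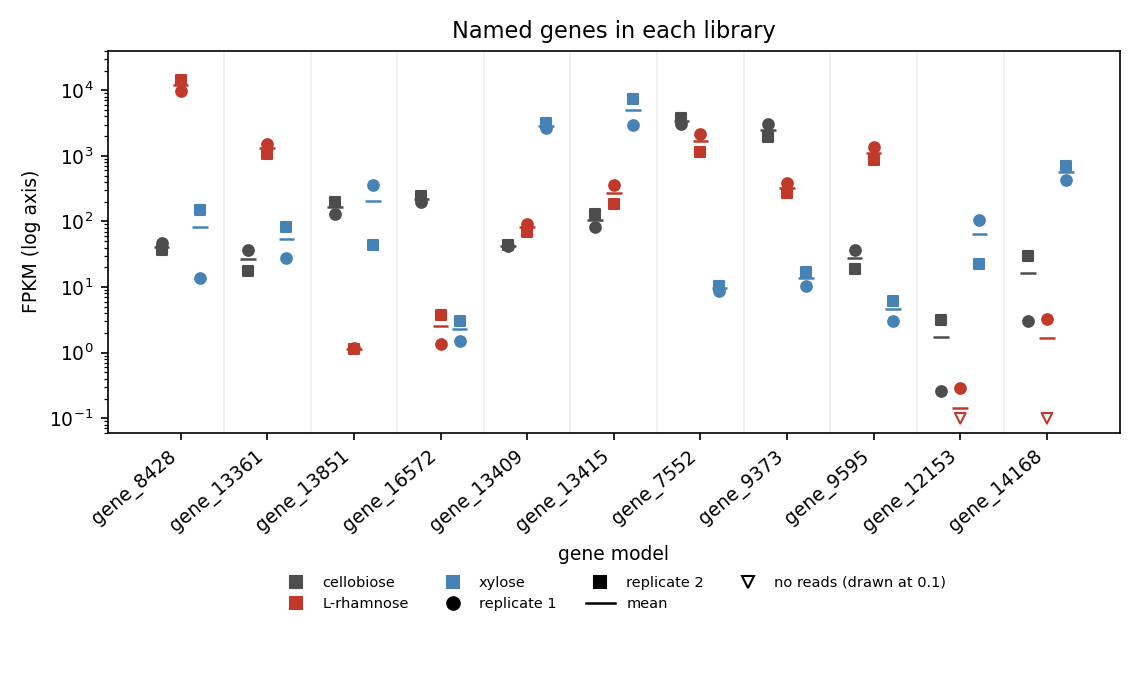
FPKM of the 11 named gene models in each of the 6 libraries on a log axis, with colour for the sugar, marker shape for the replicate and a short line for the mean of the 2 replicates. Open triangles at 0.1 are libraries without reads. The model gene_8428 lies at 9636 and 14262 FPKM on L-rhamnose and gene_7552 at 8.75 and 10.44 on xylose.

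The region on scaffold 4 between 709635 and 725642 was higher on L-rhamnose than on xylose too, with a median log2 fold change of 1.76 over its 6 models. In this comparison 50 runs of higher genes and 24 of lower genes were found, against permuted means of 17.2 and 5.72 (highest 33 and 17). Without L-rhamnose replicates 1 and 2 the 50 became 3 and 8 and the 24 became 1 and 4. Without xylose replicate 1 the 50 became 26, and without xylose replicate 2 the 24 became 42. At a minimum fold of 1.5 they were 18 and 13, and limma gave 15 and 13 runs of lower genes with a pseudocount of 1 and 0.1. At the start of scaffold 97, 6 consecutive models between 1 and 11907 had a median of 1.92, at 143 and 114 FPKM on L-rhamnose and 22.1 and 30.6 on xylose, and 3 of them share reads with other genes. Scaffold 77 carried both of the named regions lower on L-rhamnose than on xylose. The region of 5 models between 44825 and 53043 had a median of -3.26 and stood at 23.5 and 19.7 FPKM on L-rhamnose against 87.9 and 72.3 on xylose. The region of 4 models between 14253 and 26181 also had a median of -3.26, with single values from -6.69 to -1.19 (median -2.54 with limma on log2(FPKM + 1)), at 2.33 and 1.96 FPKM against 21.7 and 29.1. It was low on cellobiose too, at 3.18 and 9.36 FPKM. Between L-rhamnose and cellobiose only the model with -6.69 was called (log2 fold change -4.72), and the others, at 0.1, -0.93 and -0.02, were not. Over the whole scaffold, 22 of 53 tested genes (41.5%) were lower on L-rhamnose, against 15.6% of all genes (Fisher's exact adjusted p = 0.00167). That share was 9.09% and 10.9% without L-rhamnose replicates 1 and 2, where 264 of 12902 and 427 of 12961 tested genes were lower and the excess no longer passed (adjusted p = 0.21 and 0.345). Without either of these libraries, most genes no longer passed in the regions on scaffolds 97 and 4 and in the region from 14253 on scaffold 77. Their medians then were 1.74 and 2.08, 1.65 and 1.86, and -3.48 and -3.07.

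**Figure D3:**
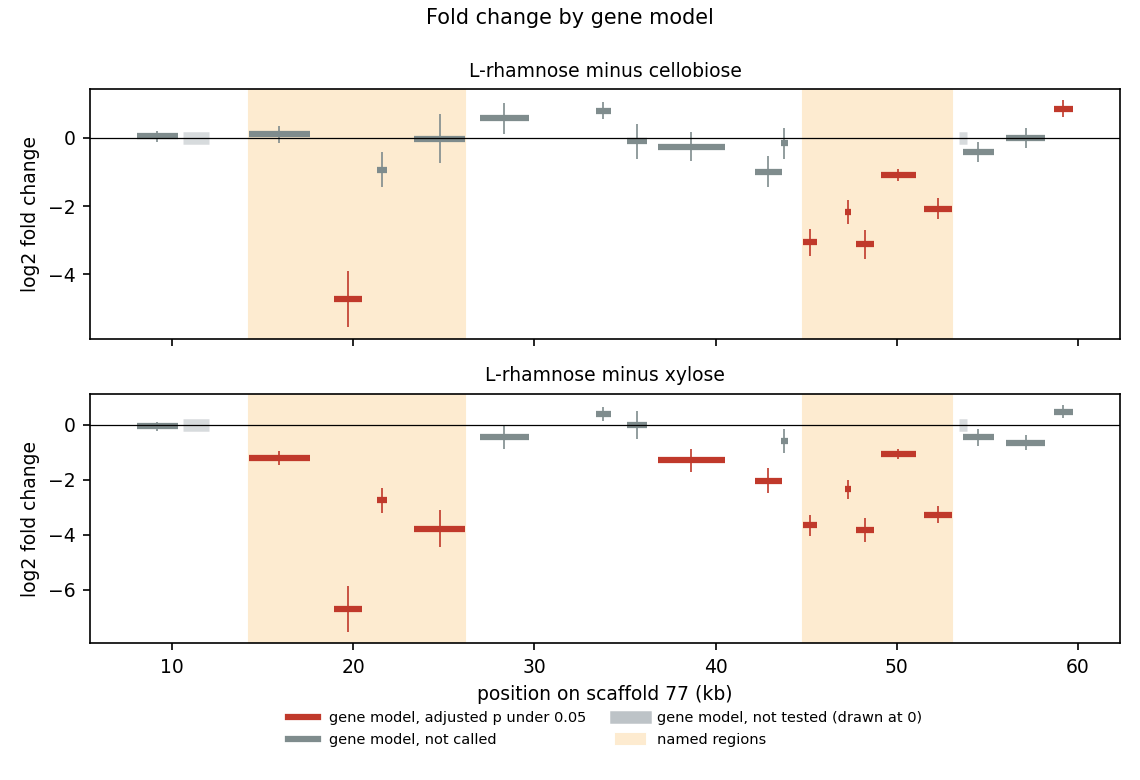
Log2 fold change (vertical axis, bars for 1 SE) of each gene model along part of scaffold 77 (horizontal axis in kb), for L-rhamnose minus cellobiose above and L-rhamnose minus xylose below. Horizontal lines span the models, in red where the adjusted p was under 0.05, and the shaded regions run from 14253 to 26181 and from 44825 to 53043. All 5 models of the right-hand region were lower on L-rhamnose in both comparisons.

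In this comparison 22% of the higher and 18.7% of the lower genes were followed by a gene called in the same direction, against permuted means of 14% and 13.8% (permutation p = 0.0001 for both). These shares were 11.4% and 8.85% without L-rhamnose replicate 1 and 13.3% and 8.55% without L-rhamnose replicate 2, above permuted means of 3.45%, 1.79%, 5.19% and 2.95% in the same order. Higher and lower genes differed in structure and in level. Median coding lengths were 960 and 1204.5 bases, and the median level of the higher genes, 18.5 FPKM over all libraries, was below that of the lower genes. Models with 1 exon made up 8.69% of the higher and 3.34% of the lower genes (Fisher's exact p adjusted over all comparisons and properties = 3.74e-12), and models with an annotated UTR 64.4% and 71.5% (adjusted p = 3.08e-06). Genes that share reads made up 12.4% and 5.52% (Fisher's exact adjusted p = 2.32e-13). Fisher's test takes genes as independent, and genes that share reads with each other may be called together. Among genes not called, the shares were 8.37% with 1 exon, 69.8% with a UTR and 8.11% sharing reads. Their median coding length was 1053 bases and their median level 21.8 FPKM. The share of 1-exon models among the higher genes was thus near that of uncalled genes, and that of the lower genes was smaller. The fold change fell with coding length (Spearman's rho -0.17 across genes), as did the difference of L-rhamnose replicate 1 from replicate 2 (-0.193). A length trend of this size thus also lay between replicates, and whether the length difference comes from the libraries was not tested. Nor were the shares with 1 exon or a UTR adjusted for level or length. Against cellobiose, 6.59% of the genes higher and 3.51% of those lower on L-rhamnose had 1 exon (Fisher's exact adjusted p = 0.000387). For xylose minus cellobiose these were 2.86% and 7.12% (adjusted p = 0.0628).

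The count of 3988 genes fell to 761 without L-rhamnose replicate 1 and to 1176 without L-rhamnose replicate 2. Higher genes made up 50.5% of the calls with TMM factors, 63.2% (2471 higher and 1439 lower) with library size only, and 65.6% with limma on log2(FPKM + 1). Library size alone moved the median log2 fold change of all genes from 0.013 to 0.161, so the even split holds relative to the median gene. Without L-rhamnose replicates 1 and 2 the share was 65.3% and 63.7%.

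To find which genes set 1 sugar apart, genes that passed both comparisons with that sugar in the same direction were counted. On L-rhamnose, 998 genes were higher than on both other sugars, with median levels of 39.0 FPKM on L-rhamnose, 13.1 on cellobiose and 11.2 on xylose. A further 960 genes were lower, with medians of 33.3, 80.5 and 81.3 FPKM. On xylose, 143 genes were higher (median 113 FPKM, against 35.8 on cellobiose and 26.7 on L-rhamnose) and 200 were lower (median 9.68 FPKM, against 48.8 and 43.2). On cellobiose, 127 genes were higher (median 58.2 FPKM, against 15.6 on L-rhamnose and 9.48 on xylose) and 70 were lower (median 43 FPKM, against 133 and 121). Changes of at least 8-fold in both comparisons were found for 44 of the genes higher and 39 of those lower on L-rhamnose, 18 higher and 29 lower on xylose, and 19 higher and 1 lower on cellobiose. A gene that passed in all 3 comparisons belongs to 2 of the groups.

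Independent lists of the same sizes would share 222 and 217 genes for L-rhamnose, 32.7 and 51.4 for xylose, and 35.6 and 23.2 for cellobiose, in the order higher and lower. In 20 simulated sets of unchanged groups at most 2 genes fell in any of the 6 groups. No gene was changed in these sets, and a comparison called at most 4 genes. They therefore cannot show how much overlap the shared libraries give when as many genes are called as here. Part of the excess over the independent lists may come from the libraries that both comparisons share.

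**Figure D4:**
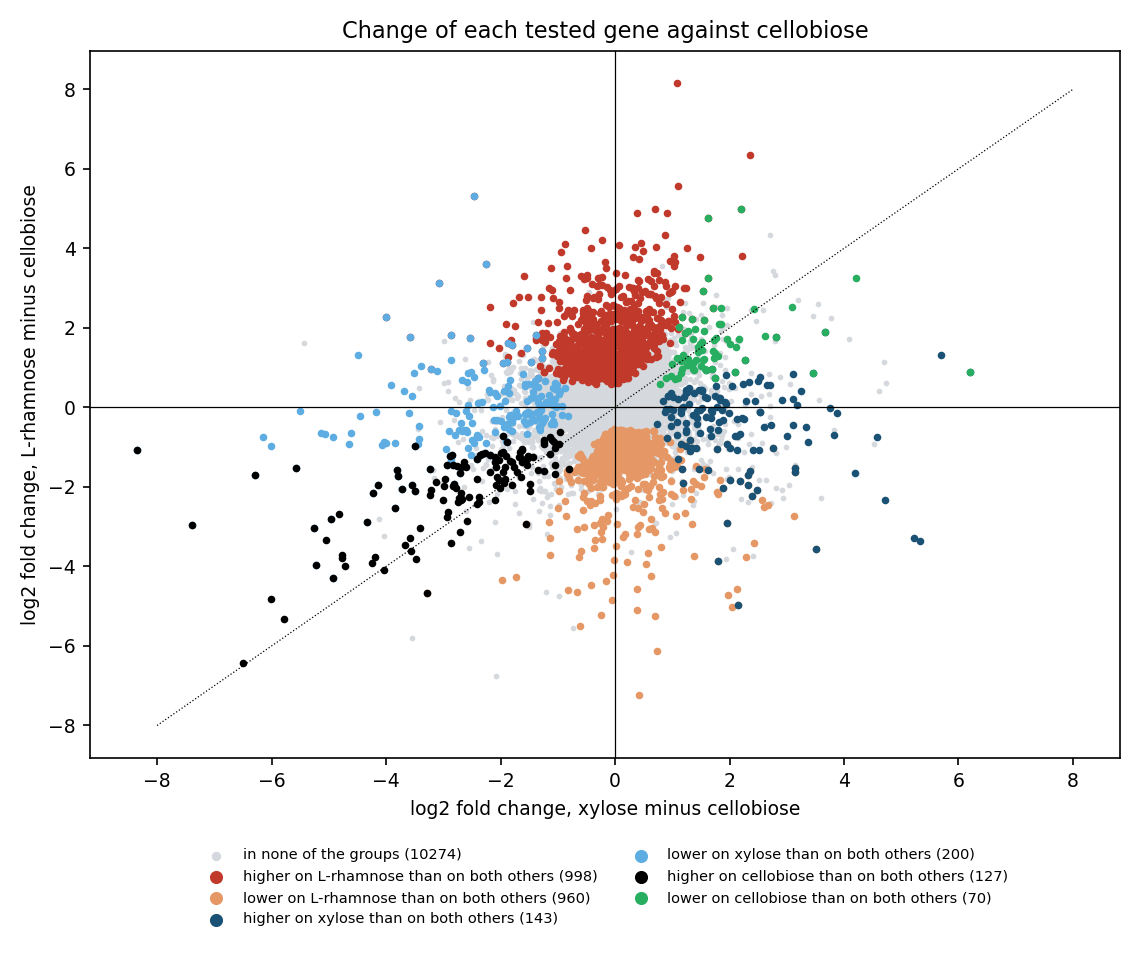
Log2 fold change of each of the 12667 tested genes on xylose (horizontal axis) and on L-rhamnose (vertical axis), both against cellobiose, with colour for the 6 groups of genes. A gene in 2 groups is drawn in the colour listed later, and the dotted line marks equal changes. The 998 genes higher on L-rhamnose lie in the upper part and the 127 genes higher on cellobiose at the lower left.

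These group sizes moved with single libraries. Without cellobiose replicates 1 and 2 and L-rhamnose replicates 1 and 2, in this order, the 998 genes higher on L-rhamnose numbered 463, 153, 94 and 126 and the 960 lower ones 438, 104, 16 and 24. The 143 genes higher on xylose numbered 22, 66, 32 and 31. The 200 genes lower on xylose numbered 73 without cellobiose replicate 1, 53 and 60 without L-rhamnose replicates 1 and 2, and 0.525 times the 200 without cellobiose replicate 2. Without the libraries named first, the 127 genes higher on cellobiose numbered 69, 45, 18 and 22 and the 70 lower ones 3, 3, 6 and 9. Without xylose replicates 1 and 2, 238 and 197 genes were higher and 176 and 113 lower on cellobiose, and without replicate 2, 441 were higher and 325 lower on xylose. With library size only as the scaling, the genes set apart on xylose were 114 higher and 273 lower, and with DESeq2 they were 332 higher and 320 lower. On cellobiose, DESeq2 gave 201 higher genes and 2.17 times the 70 lower ones.

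The 10 most abundant transcripts differed most between L-rhamnose and xylose. The 10 genes with the highest mean FPKM on L-rhamnose ranged from 4447 to 27205 FPKM, and 8 of them were called lower on xylose, where their median was 1184 FPKM against 8005 on L-rhamnose. Of the 10 highest on xylose, from 3591 to 6990 FPKM, 7 were called lower on L-rhamnose, and 0 genes were in both sets of 10. The 10 highest on cellobiose, from 3840 to 19028 FPKM, shared 3 genes with the L-rhamnose set and 1 with the xylose set, and 6 of them share reads with other genes. Of the cellobiose set, 1 was called lower and 1 higher on L-rhamnose and 3 lower on xylose. On cellobiose 5 of the L-rhamnose set and 3 of the xylose set were called lower. Genes that share reads numbered 3 in the L-rhamnose set and 2 in the xylose set. Each set was picked as highest on its sugar in these same libraries, so lower levels on another sugar are partly fixed by that choice.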

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

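The gap between neighbours, the removal of genes that share reads, the tests of regions and scaffolds, the repeats of these and of the neighbour test in the other fits, and counting the higher and lower genes of a sugar together in this part, were chosen after seeing the data. Of 178 values of the 12 named gene results under the alternatives, 170 kept their direction and stayed past the threshold, 8 lost the threshold and 0 reversed. The named genes were picked for the greatest changes, with both libraries of one sugar above both of the other. A reversal was thus hardly possible. The minimum fold was applied to counts, runs, neighbours and scaffolds only, and gene_12153 and gene_14168 had no value at 1 CPM in 4 libraries. All 8 losses came from leaving out 1 library and concern gene_8428, gene_13851 and gene_12153. For the 10 named region results, most of the genes lost the threshold in 23 of 150 values and did not in 127, and 0 reversed. The regions were picked as runs in which each model passed with at least a 2-fold change, so their reversal was hardly possible either. Tests of the 33 gene lists and of product names, with their alternatives, were not run because no list could be formed.

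Leaving out 1 library gave between 149 and 3802 genes for L-rhamnose minus cellobiose (2792 with all), 148 and 1035 for xylose minus cellobiose (533) and 761 and 4124 for L-rhamnose minus xylose (3988). Genes set apart on 1 sugar, higher or lower than on both others, ranged from 110 to 2463 for L-rhamnose (1958), 85 to 766 for xylose (343) and 24 to 414 for cellobiose (197). A sugar left with 1 library is assumed to vary like the other groups, and the cause of these ranges was not tested. Shares of neighbours ranged from 0.0% to 20.8% for genes lower on L-rhamnose than cellobiose, and from 0.0% to 10.6% for genes higher on xylose than cellobiose.

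Against a minimum fold of 1.5, by construction a stricter test, the counts were 805, 259 and 1643. A fit of only the 2 sugars gave 191 genes for xylose minus cellobiose, 129 genes set apart on xylose, 104 on cellobiose, and a neighbour share of 1.67% for genes higher on xylose than cellobiose. DESeq2 gave 1079 genes for xylose minus cellobiose, 652 set apart on xylose and 353 on cellobiose. The cause of either was not tested. The fit of all 6 libraries assumes that a gene varies alike on all sugars. Replicates differed most on xylose, with a chi-square per degree of freedom of 53.83, against 24.32 on cellobiose and 14.76 on L-rhamnose. The adjusted p-values of that fit for xylose minus cellobiose may therefore be too small. For neighbours at least 1000 bases apart, with fewer genes tested, the shares were 0.0% for genes higher and 4.9% for genes lower on xylose than cellobiose. DESeq2 size factors, library size alone, limma on FPKM and both other filters on low counts moved none of these counts by over 1.5 times with both directions together. By direction, limma gave 136 and 127 genes higher on xylose than cellobiose (210) and 1252 and 1222 lower on L-rhamnose than xylose (1974), with a pseudocount of 1 and 0.1. Likewise it gave 91 and 83 genes higher on xylose than on both others (143), and 627 lower on L-rhamnose (960) with the smaller pseudocount. The 2-sugar fit gave 41 higher and 88 lower on xylose and 77 and 27 on cellobiose, against 143, 200, 127 and 70. DESeq2 gave 201 higher on cellobiose (1.58 times) and 2.17 times as many lower.

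With the replicate number as a block, 1597, 373 and 2852 genes passed in the order above, 1127 were set apart on L-rhamnose (632 higher, 495 lower) and 129 on cellobiose (93 and 36). Of the run on scaffold 52 from 190493, 1 of 3 genes passed against cellobiose. Libraries of the same number did not deviate together (correlations of deviations -0.227, -0.14 and -0.101), and with 2 numbers per sugar they share only a number.

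In simulated data with 2500 changed genes, 55.8%, 53.7% and 55.8% of 2-fold changes were found at this depth and number of libraries. With 200 changed genes the shares were 19%, 6% and 13%, in the same order of comparisons. Recovery thus depends on how many genes change, and genes that differ 2-fold can be missed.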

Other observations

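The gap between neighbours, the removal of genes that share reads and the regions on scaffold 52 named here were chosen after seeing the data. Genes higher on L-rhamnose formed 3 runs along scaffold 52, which is 198264 bases long. The runs hold 3 models between 100916 and 107463, 4 between 170449 and 179203, the last of which is gene_9595, and 3 between 190493 and 196351. Their median log2 fold changes were 3.51, 3.63 and 2.04 against cellobiose and 4.64, 3.23 and 3.75 against xylose. Without xylose replicate 2 the 3.23 was 4.05, and without xylose replicates 1 and 2 the 3.75 was 3.08 and 4.47 (3.1 with limma on log2(FPKM + 1)). Mean levels of the run that ends with gene_9595 were 375 and 245 FPKM in the L-rhamnose libraries, 13.1 and 6.98 in the cellobiose libraries and 2.65 and 5.62 in the xylose libraries, and none of its genes shares reads. Most of the L-rhamnose level is gene_9595, and the other 3 models averaged 46.2 and 33.5, 5.24 and 3.09, and 2.5 and 5.44 FPKM. Against cellobiose, 3 of its 4 genes passed without cellobiose replicate 2, L-rhamnose replicate 1 or L-rhamnose replicate 2, and against xylose 3 without L-rhamnose replicate 1. Of the run from 100916, 2 of 3 genes passed against cellobiose without L-rhamnose replicate 1. Of the run from 190493, 0 of 3 passed against cellobiose without cellobiose replicate 2 or either L-rhamnose library and 1 without cellobiose replicate 1, and 2 passed against xylose without either L-rhamnose library. Against cellobiose, 1 of these 3 passed at a minimum fold of 1.5 and 2 with limma on log2(FPKM + 0.1). Runs of at least 3 genes higher on L-rhamnose than cellobiose numbered 15 with all libraries (permuted mean 5.38), 0 and 1 without L-rhamnose replicates 1 and 2, and 5 and 2 without cellobiose replicates 1 and 2. No model of these runs has a product name in the files, so what the genes encode is not given in the sources used here.

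Neighbouring genes were called in the same direction more often than permuted calls in L-rhamnose against xylose. If reads of a gene were counted in an overlapping neighbour, the excess should vanish for neighbours at least 1000 bases apart. Among these, 18.8% of lower genes were followed by another lower gene, above the highest of 10000 permutations (18.5%). If near-identical copies that share reads made the excess, it should vanish without such genes, but the share was then 18.6%, against a highest permuted share of 16.6%. For higher genes the shares were 20.5% (highest permuted 18.4%) and 19.8% (15.8%). In the other comparisons the excess for neighbours at least 1000 bases apart was not above every permutation: 14.1% and 11.8% for genes higher and lower on L-rhamnose than cellobiose (highest permuted 16.7% and 14.7%), and 0.0% and 4.9% for xylose against cellobiose (11.1% and 9.47%). For L-rhamnose against cellobiose an excess over the permuted means still passed at this distance (permutation p = 0.0016 and 0.0466), the latter narrowly. For xylose against cellobiose it did not pass. Overlapping reads are thus not excluded as a source of part of the excess in either comparison. Shared regulation of neighbouring genes on these sugars stays a hypothesis that was not tested.

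Genes that share reads were more often higher than lower on L-rhamnose against xylose (12.4% and 5.52%, odds ratio 2.41, with 8.11% among genes not called). If this came from lower expression of the higher genes, it should shrink when expression and coding length enter a logistic model. The adjusted odds ratio was 2.3 (95% interval 1.76 to 3.0), close to 2.41, so these properties changed the estimate little. The model takes genes as independent. Genes that share reads with each other may be called together, so the interval may be too narrow. How RSEM divided reads among copies was not tested and could contribute to the 2.3.

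Between the replicates of a sugar, genes were counted that lay higher in replicate 2, with no test. On xylose these were 60% of the 200 genes lower and 47.6% of the 143 higher on that sugar, against 50.1% of all tested genes. On cellobiose they were 50.0% of the 70 lower and 62.2% of the 127 higher genes, against 49.0%, and on L-rhamnose 47.7% of the 960 lower and 36.2% of the 998 higher genes, against 46.0%.

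Across genes, Spearman's rho of the log2 difference with coding length was -0.17 for L-rhamnose minus xylose, -0.139 for L-rhamnose minus cellobiose and 0.075 for xylose minus cellobiose. Between replicates 1 and 2 it was -0.193 on L-rhamnose, 0.124 on xylose and 0.028 on cellobiose.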
